A study of Homo sapiens with 40 samples.

How the data were processed

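The samples were 40 RNA-seq libraries from 10 human non-small cell lung cancer cell lines, with 2 libraries for DMSO and 2 for GSK3368712 in each line. Per the labels' protocols, RNA was isolated with a miRNeasy kit, libraries were made with the TruSeq Stranded mRNA kit, and sequencing gave paired reads of 151 bases at a stated depth of 100000000 per sample. Per the submitters' processing notes, reads were checked with FastQC, quantified with Salmon 0.12.0 against GRCh38 and compared with DESeq2 (version not stated), and each comparison was filtered at an FPKM of 1. The sample titles end in D5, whose meaning is not spelled out. Subtype (LUAD or LUSC) was taken from the row labels of the table.

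The only values used were those of the authors' deposited table of DESeq2 comparisons. It holds 58336 genes for each of 10 lines, and 135786 of its 583360 entries have values. The authors' deposited fold changes and their standard errors are in log2 units. The deposited test statistic is a score, equal to the log2 fold change over its standard error within 0.166. The deposited adjusted p is a p-value adjusted by Benjamini-Hochberg over the genes listed for a line, and recomputing it changed the number of calls by at most 3 per line. The authors' mark was checked to equal an adjusted p of at most 0.05 with an absolute log2 fold change of at least 1 in 135777 of the 135786 entries. The table also gives mean normalized counts per gene and line. The direction of the fold changes (GSK3368712 over DMSO) was read from the order of the names in the row labels and could not be checked from the values. Values per library were not analysed here. The sum of mean normalized counts was 57647556 to 108557964 per line, and library depth was not analysed here, so no counting interval is given. The labels do not state whether the 2 libraries of an arm are separate cultures, so they may be technical replicates.

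Gene symbols came from the authors' deposited table, and positions, gene types, GC content and the length of the longest transcript from GENCODE 29. Of 19280 gene IDs with values, 19245 (99.8%) matched. Statistics were run in R 4.3.3 with limma 3.58.1, and figures in Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9. Genes per line were counted from the authors' adjusted p at a threshold of 0.05. Across lines, limma tested the mean log2 fold change of each of the 9339 genes with values in all 10 lines, with 1 fold change per line and Benjamini-Hochberg adjustment. Values given as mean ± SD are over lines, of the authors' fold changes.

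Gene lists (36, fixed together with the tests and the rule for named genes before the data were examined) were tested when at least 3 members had values. Across lines, the mean of the members per line was tested against 0 by an exact two-sided sign-flip permutation test over 1024 sign assignments, whose smallest p is 0.00195, and by camera with a preset correlation of 0.01 and with an estimated one. Both were adjusted over the 28 lists tested. A single list at the smallest sign-flip p has an adjusted p of 0.0547, so no list could pass that test alone. Within a line, camera was run on the deposited statistic, adjusted over 341 tests. Differences between lines were tested by Cochran's Q with the authors' standard errors. Pearson correlations were computed across genes for 45 pairs of lines. The comparison of LUAD with LUSC lines by limma was added after the row labels were seen.

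Genes named across lines are the 12 with the largest positive and the 12 with the largest negative mean among those past the test with the same sign in at least 9 of 10 lines. Per list, all members of lists of up to 6 measured genes and up to 4 members with the smallest p of longer lists could be named. PRMT1, CARM1, PRMT6, DNMT1, CD274, B2M, CDKN1A and MKI67 were always followed. The results of a few further genes that these rules take are not reported. Per line, the 2 largest positive and 2 largest negative fold changes past the authors' adjusted p were taken among genes above the line's median expression. Between lines, the 6 genes with the largest Q among those with a line above 1 and a line below −1 were taken. Genes without a symbol were left out.

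Alternatives tried were recomputed adjustment, the top 75% of genes by expression, centring, genes in at least 7 lines, a random-effects meta-analysis, an ordinary one-sample test, robust and trended variance, scaling by each line's SD, medians of lists, and leaving out each line. Correction for GC content and length, omission of NCIH1975, NCIH522 and PC9, and fits of each subtype alone were added after the data were seen. The tests were tested on simulated data: the test across lines recovered 72% of genes shifted by 0.5 and 100% of those shifted by 1, with 5.49% false calls. Cochran's Q recovered 95.5% with 6.83% false calls. The subtype test recovered 71% at a difference of 1 and 97% at 2, with 6.15% false calls. The sign-flip test called 3% of 100 random lists. The simulated genes were drawn independently, with the authors' standard errors taken as true and without trends on GC content or length. The rates therefore do not cover correlated genes, such trends or wrong standard errors.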

Results

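Gene expression was measured by RNA sequencing in 40 libraries from 10 human non-small cell lung cancer cell lines. Each line was treated with the vehicle dimethyl sulfoxide (DMSO) or with GSK3368712, an inhibitor of the type I arginine methyltransferases, and each arm of a line had 2 libraries. The row labels assign 6 lines to lung squamous cell carcinoma (LUSC: EBC1, LK2, NCIH226, NCIH520, SKMES1 and SW900) and 4 lines to lung adenocarcinoma (LUAD: NCIH1563, NCIH1975, NCIH522 and PC9). The values analysed were the log2 fold changes, standard errors and adjusted p-values of the authors' deposited table, which compares the compound with DMSO in each line. A positive value is read as higher with GSK3368712, from the order of the names in the row labels, because the direction is not spelled out. Between 12721 and 14565 genes per line had values in the authors' deposited table, and 9339 genes had values in all 10 lines. The mean normalized counts summed over the listed genes lay between 57647556 and 108557964 per line. The depth of each library was not analysed here.

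The first comparison asked which genes changed with GSK3368712 in each cell line. The genes named in this comparison have the largest changes past the authors' adjusted p among genes above the line's median expression. In EBC1, the authors' deposited table lists LBH, a transcriptional cofactor, at a log2 fold change of 4.91 and ID3, an inhibitor of basic helix-loop-helix factors, at 4.50. In the same line, the authors' deposited table gives −2.43 for NT5E, the ectonucleotidase CD73 that makes adenosine, and −2.04 for PLXNA4, a semaphorin receptor. In NCIH1563, DGCR11, a transcript from within an intron of DGCR2, stood at 5.41 and CRYAB, a small heat shock protein, at 4.26 in the authors' deposited table. The authors' deposited table places HDAC4, a class IIa histone deacetylase, at −4.87 and BDKRB2, a bradykinin receptor, at −4.06 in NCIH1563. In SW900, the authors' deposited table has KRT4, a keratin of squamous epithelia, at 4.32.

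In NCIH226, FN1 (fibronectin) reached 3.62 and SLAMF7 3.24 in the authors' deposited table. CEMIP, which takes part in hyaluronan breakdown, reached 3.32 and BMF, a pro-apoptotic BCL2 family member, 3.31 in SKMES1 in the authors' deposited table. STC1 stood at −2.51 and HAS3, a hyaluronan synthase, at −2.45 in SKMES1 in the authors' deposited table. HADH, an enzyme of mitochondrial fatty acid oxidation, stood at −2.54 in LK2 and −1.89 in NCIH226 in the authors' deposited table. LK2 had ASS1, an enzyme of arginine synthesis, at 2.36 and the nuclear RNA MALAT1 at 1.97 in the authors' deposited table, with DNAH9 at −2.02. CDH4 stood at −1.89 in NCIH226 in the authors' deposited table. In NCIH520, the authors' deposited table gives 1.28 for SNHG19, 1.13 for CHML, −2.04 for OPN3 and −1.58 for PRKACB, a catalytic subunit of protein kinase A. SW900 had AQP3 at 1.71, GLIPR1 at −1.93 and the linker histone gene H1FX at −1.84 in the authors' deposited table.

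In NCIH1975 and PC9, placental-type alkaline phosphatase genes led. ALPG stood at 4.46 and ALPP at 3.76 in NCIH1975, and ALPP at 2.18 in PC9, in the authors' deposited table. ALPG and ALPP are near-identical paralogs, so the assignment of reads between them is uncertain. VGF, a secreted neuroendocrine peptide precursor, stood at −3.31 in NCIH1975 in the authors' deposited table. HEG1 at 1.70, PADI3 at −1.70 and ATL3 at −1.65 followed in PC9 in the authors' deposited table. Among genes above the median expression of NCIH522, GAREM2 stood at 1.28, ASIC1 at 1.20, COA5 at −1.38 and MRM1 at −1.43 in the authors' deposited table. The standard errors of the 40 values that this choice of genes takes lay between 0.082 and 0.578 in the authors' deposited table.

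By the authors' DESeq2 adjusted p, 3214 genes were higher and 3270 lower in EBC1, which is 46.4% of the genes listed. The counts were 2727 and 2673 in LK2, 2025 and 2072 in NCIH226, 1614 and 1742 in NCIH520, 2267 and 2246 in SKMES1, and 2617 and 2585 in SW900. Among the adenocarcinoma lines, NCIH1563 had 3105 higher and 3298 lower genes (48.1% of those listed), NCIH1975 562 and 464, PC9 326 and 243, and NCIH522 118 and 97 (1.66%). The authors' mark for a log2 fold change of at least 1 in either direction was set for 2428 genes in NCIH1563, 1236 in EBC1 and 137 in NCIH522. The median standard error over the genes shared by all lines was 0.092 to 0.115 in the LUSC lines, 0.201 in NCIH1563, 0.244 in NCIH522, 0.294 in PC9 and 0.316 in NCIH1975, so counts of calls are not comparable as sizes of response. The labels do not say whether the 2 libraries of an arm came from separate cultures, so these adjusted p-values reflect only the spread between libraries.

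**Figure D1:**
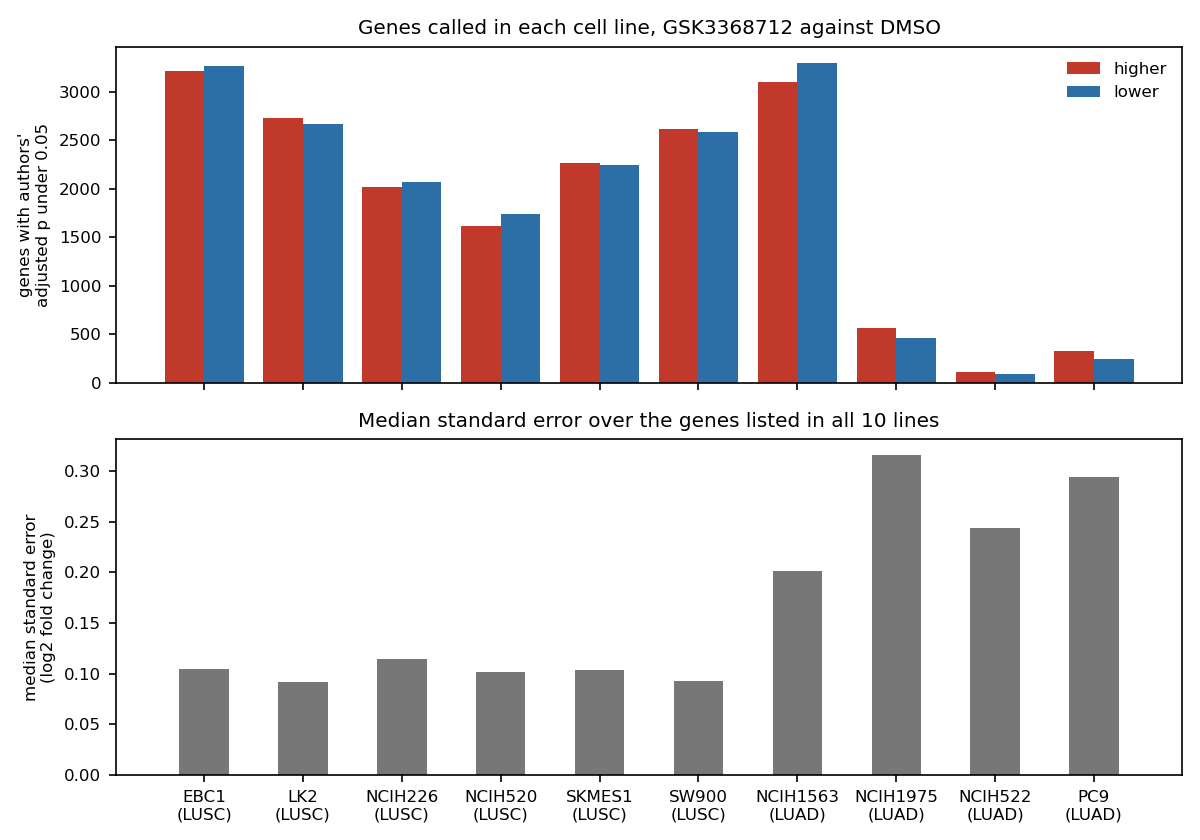
Number of genes called higher and lower with GSK3368712 by the authors' DESeq2 adjusted p in each cell line. NCIH522 had 215 calls and EBC1 6484, and the LUAD lines other than NCIH1563 had the fewest.

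The second comparison asked which genes changed across the 10 lines, with the line as the replicate. The transcript with the largest rise was DGCR11 (ENSG00000273311, GRCh38 chromosome 22, 19046162 to 19048375, in an intron of DGCR2), at a mean log2 fold change of 3.27 ± 0.94 (SD, n = 10; limma adjusted p = 7.84e-06). Of the 9339 genes with values in every line, only this one was called higher in each by the authors. Among protein-coding genes, GSDMB, a member of the pore-forming gasdermin family, rose by 1.41 ± 0.63 (n = 10; limma adjusted p = 0.000154). LAT, an adaptor of T cell receptor signalling, rose by 1.36 ± 0.58 (limma adjusted p = 0.000139), and PPARA, a nuclear receptor of fatty acid metabolism, by 1.12 ± 0.46 (limma adjusted p = 0.000125). Both were higher in 10 of 10 lines, and both overlap another annotated gene on the same strand, so their read assignment is uncertain. HDAC5, a class IIa histone deacetylase, rose by 1.26 ± 0.96 (limma adjusted p = 0.00391).

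Non-coding RNAs made up much of the top of the list. NEAT1, the scaffold RNA of paraspeckles, rose by 1.26 ± 0.81 (n = 10; limma adjusted p = 0.00145) and was higher in 9 of 10 lines. The snoRNA host transcripts SNHG19 and SNHG8 rose by 1.22 ± 0.43 and 1.10 ± 0.40 (limma adjusted p = 4.66e-05 and 6.12e-05), each in 10 of 10 lines. GABPB1-IT1, which lies within GABPB1, rose by 1.14 ± 0.42 (limma adjusted p = 6.35e-05). ATP6V1G2-DDX39B, a readthrough of a pair of neighbouring genes, stood at 1.64 ± 0.77, RPL32P29, a pseudogene inside RPS29, at 1.22 ± 1.07, and LY6G5B, which overlaps CSNK2B, at 1.09 ± 0.30 (limma adjusted p = 0.000204, 0.00814 and 1.53e-05). The assignment of reads to these 3 genes, to DGCR11 and to GABPB1-IT1 is uncertain because each overlaps another gene on the same strand. Of the 269 long non-coding genes, 46.1% passed the test across lines, 68 higher and 56 lower, against 20.8% of the protein-coding genes. The median of their mean log2 fold changes was 0.022, so this share is not a general rise. The odds ratio of long non-coding against all other genes was 3.23 (Fisher's exact p = 1.55e-19, with genes not independent). Long non-coding genes had a median expression of 362 normalized counts, against 2979 for protein-coding genes, and the shares were not matched on expression.

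The gene with the largest fall was OPN3 (ENSG00000054277, chromosome 1, 241590102 to 241677376), a non-visual opsin, at −1.98 ± 0.74 (n = 10; limma adjusted p = 4.73e-05). The authors called it lower in 10 of 10 lines. OPN3 overlaps CHML on the same strand, and CHML, a Rab escort protein gene, had positive fold changes in each of the 9 lines that list it. TMEM107 (ENSG00000179029, chromosome 17, 8173237 to 8176399), a protein of the ciliary transition zone whose gene overlaps the snoRNA SNORD118, fell by 1.54 ± 0.22 (limma adjusted p = 1.62e-07). MRM1, a mitochondrial ribosomal RNA methyltransferase, fell by 1.47 ± 0.31 (limma adjusted p = 2.32e-06), and TST, a mitochondrial sulfurtransferase, by 1.32 ± 0.33 (limma adjusted p = 7.84e-06). ADCY3, an adenylyl cyclase, fell by 1.29 ± 0.46 (limma adjusted p = 4.66e-05). HDAC4 fell by 1.29 ± 1.36 in 9 of 10 lines (limma adjusted p = 0.0202), while its paralog HDAC5 rose. With an ordinary test in place of limma the call for the gene HDAC4 was lost (adjusted p = 0.0678), and without NCIH1563 its mean was −0.89.

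LRP11 fell by 1.45 ± 0.91, CCDC92 by 1.33 ± 0.87 and CCDC78 by 1.35 ± 0.72 (n = 10; limma adjusted p = 0.00117, 0.00161 and 0.000415), the last in 9 of 10 lines. LRP11 and CCDC92 overlap other annotated transcripts on the same strand, so their read assignment is uncertain too. SCOC-AS1, TMPO-AS1 and TYMSOS, which lie antisense to or share a promoter with SCOC, TMPO and TYMS, fell by 1.47 ± 0.35, 1.37 ± 0.59 and 1.32 ± 0.86 (limma adjusted p = 5.32e-06, 0.00014 and 0.00147). The strand used for counting is not stated, so values of these antisense transcripts are uncertain. Besides OPN3, TMEM107, MRM1 and TST, 4 genes were called lower by the authors in every line and were picked out after their values were seen. These were CYB5D2 at −1.20, ATP6V1E2 at −1.18, ABI2 at −0.86 and ATL3 at −0.85 (limma adjusted p = 0.000239, 0.000424, 0.000946 and 0.003).

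**Figure D2:**
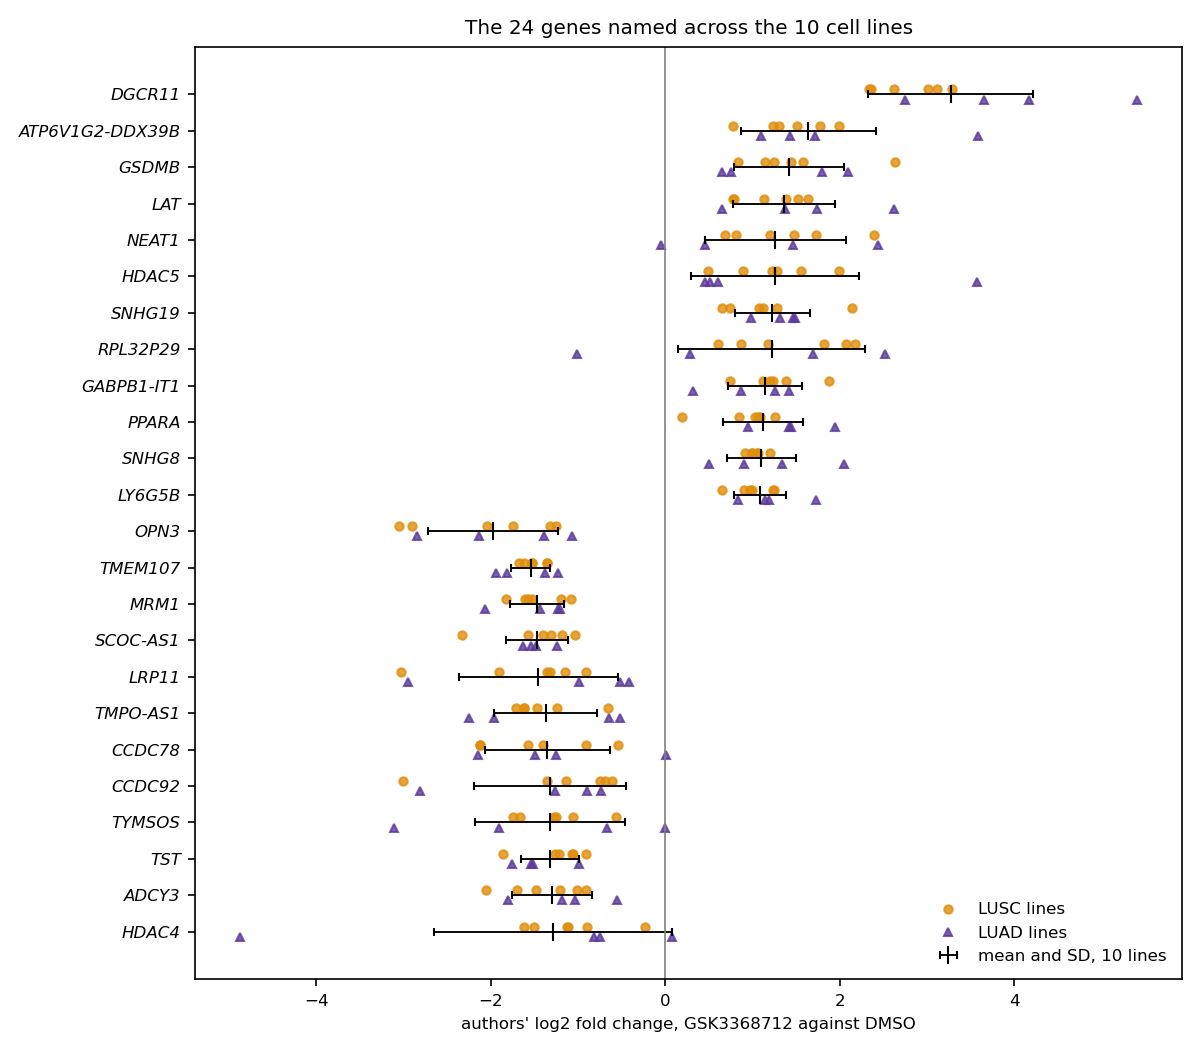
Log2 fold change of the 12 genes with the largest mean rise and the 12 with the largest mean fall, with 1 point per cell line and the mean and SD over the 10 lines. TMEM107 varied least, at −1.54 ± 0.22, and HDAC4 most, at −1.29 ± 1.36.

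Across the 9339 genes, 887 rose and 1134 fell, which is 21.6% of the genes tested, and 3230 passed an unadjusted p under 0.05. Of these, 393 rose and 489 fell with the same sign in all 10 lines. A mean log2 fold change of at least 1 was reached by 23 of the genes that rose and of at most −1 by 29 of the genes that fell. In the 6 LUSC lines alone, 1060 rose and 1446 fell. In the 4 LUAD lines alone, 4 genes passed limma's adjusted p (950 unadjusted).

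The target enzyme PRMT1 stood at 0.10 ± 0.23 (n = 10; limma adjusted p = 0.416) and CARM1 at 0.11 ± 0.35 (adjusted p = 0.502), or 0.011 without NCIH1563. PRMT3 fell by 0.41 ± 0.25 (limma adjusted p = 0.00364), and PRMT2 stood at 0.19 ± 0.20 (adjusted p = 0.0753). Of the 4 measured type I PRMT genes, 0 rose and 1 fell, and adjusted over the list alone 1 rose and 1 fell. The list had a mean of −0.004 ± 0.127 and a sign-flip adjusted p of 0.92. Of the 9 genes of other arginine methyltransferases and the methionine cycle, 0 changed over all genes and 0 adjusted over the list alone, with PRMT9 at −0.35 and WDR77 at −0.15 (list mean −0.01 ± 0.09, sign-flip adjusted p = 0.795). PRMT6 had values in 9 lines.

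The third comparison asked whether gene groups fixed before the data were examined changed across the lines. Of 36 lists, 28 had at least 3 members with values in all 10 lines. This left 3 of 31 mesenchymal and matrix, 5 of 23 epithelial junction and 4 of 24 interferon gamma response genes. It left 15 of 41 type I interferon response and 7 of 22 nucleic acid sensing genes, so these tests cover only part of each group. With values in at least 7 lines, 23 mesenchymal genes had a mean of 0.27 ± 0.33 and 11 interferon gamma genes 0.24 ± 0.23 (sign-flip adjusted p = 0.106 for each). Interferon and antigen presentation genes split by member. Of 15 type I interferon response genes, 5 rose and 1 fell, also when adjusted over the list alone. IRF7, a transcription factor of the interferon response, rose by 0.63 ± 0.61 (n = 10; limma adjusted p = 0.0152), UBE2L6, which conjugates ISG15, by 0.51 ± 0.50 (adjusted p = 0.0194), and SP110 by 0.35 ± 0.29 (adjusted p = 0.0156). The list mean was 0.17 ± 0.34, above 0 in 8 of 10 lines (sign-flip adjusted p = 0.333, camera adjusted p = 0.311). Of 4 interferon gamma response genes, 1 rose, also adjusted over the list alone: IRF1, by 0.36 ± 0.41 (limma adjusted p = 0.0438). WARS stood at 0.17 ± 0.56, APOL2 at 0.11 ± 0.44 and RNF213 at 0.03 ± 0.65, and the list at 0.17 ± 0.22 (sign-flip adjusted p = 0.203).

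Of 16 MHC class I presentation genes, 3 rose and 1 fell, also adjusted over the list alone. HLA-E, a ligand of natural killer cell receptors, rose by 0.58 ± 0.32 (n = 10; limma adjusted p = 0.00119), HLA-B by 0.39 ± 0.44 (adjusted p = 0.0374) and HLA-C by 0.28 ± 0.27 (adjusted p = 0.0316). HLA genes are polymorphic paralogs, so the assignment of reads between them is uncertain. TAP2, a subunit of the peptide transporter, fell by 0.24 ± 0.21 (limma adjusted p = 0.0365), and B2M stood at 0.14 ± 0.24 (adjusted p = 0.226). As a whole, the list stood at 0.09 ± 0.18 (sign-flip adjusted p = 0.328). Of 7 nucleic acid sensing genes, MAVS, the mitochondrial adaptor of RNA sensing, rose by 0.32 ± 0.10 (limma adjusted p = 0.00167) and 6 did not pass, with the same counts adjusted over the list alone (list mean −0.03 ± 0.16, sign-flip adjusted p = 0.682). Of 7 checkpoint and costimulatory ligands, CD58, the ligand of CD2 on T cells, fell by 0.38 ± 0.24 (limma adjusted p = 0.00476), and 6 did not pass, also adjusted over the list alone (list mean −0.05 ± 0.21, sign-flip adjusted p = 0.677). MICB stood at 0.26 ± 0.34 and CD47 at −0.20 ± 0.38. CD274, which encodes PD-L1, had values in 6 lines of the authors' deposited table, from −1.12 in EBC1 to 0.64 in NCIH226. The 8 NF-kB targets had 0 members past the test over all genes and 0 adjusted over the list alone, with IER3 at 0.32 ± 0.63 (list mean 0.09 ± 0.15, sign-flip adjusted p = 0.203).

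Of 14 genes of DNA methylation and silencing, 2 rose and 3 fell, also adjusted over the list alone. DNMT1, the maintenance DNA methyltransferase, fell by 0.37 ± 0.26 in 9 of 10 lines (n = 10; limma adjusted p = 0.0075), and EHMT1, a histone H3 lysine methyltransferase, by 0.33 ± 0.29 (adjusted p = 0.0188). DNMT3B, a de novo DNA methyltransferase, rose by 0.33 ± 0.31 (limma adjusted p = 0.0235), and MORC2 by 0.34 ± 0.27 (adjusted p = 0.0128). Their mean was −0.06 ± 0.14 (sign-flip adjusted p = 0.386).

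Cell cycle genes were lower in most lines. Of 36 genes of mitosis and G2/M, 11 fell and 0 rose, and adjusted over the list alone 16 fell. HMMR fell by 0.65 ± 0.43, the spindle checkpoint kinase BUB1 by 0.49 ± 0.33, and the kinesins KIF20B and KIF11 by 0.40 ± 0.20 and 0.37 ± 0.24 (n = 10; limma adjusted p = 0.00256, 0.00372, 0.00205 and 0.00597). The mitosis list had a mean of −0.24 ± 0.25, below 0 in 9 of 10 lines (camera adjusted p = 6.66e-06, sign-flip adjusted p = 0.137). Camera lost that call when the correlation was estimated (adjusted p = 0.987 with an estimated correlation). Of 34 genes of DNA replication and G1/S, 7 fell and 0 rose, also adjusted over the list alone. Among them the primase subunit PRIM1 fell by 0.54 ± 0.36, cyclin gene CCNE2 by 0.48 ± 0.39 and the ribonucleotide reductase subunit RRM2 by 0.47 ± 0.41 (limma adjusted p = 0.00299, 0.00834 and 0.0119). That list had a mean of −0.23 ± 0.29 (camera adjusted p = 0.000154, sign-flip adjusted p = 0.203, camera adjusted p = 0.987 with an estimated correlation). Of 27 genes of homologous recombination and the Fanconi pathway, 6 fell and 0 rose, also adjusted over the list alone. RAD54B fell by 0.64 ± 0.52, BLM by 0.45 ± 0.41 and RAD50 by 0.43 ± 0.33 (limma adjusted p = 0.00723, 0.0143 and 0.00829), with a list mean of −0.15 ± 0.19 (camera adjusted p = 0.0503, sign-flip adjusted p = 0.203). MKI67, the proliferation marker, stood at −0.24 ± 0.66 (limma adjusted p = 0.378), at −0.074 without NCIH1563 and −0.37 without PC9.

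Of 18 p53 targets, 4 rose and 2 fell, also adjusted over the list alone. DDB2, a DNA damage recognition factor, fell by 1.00 ± 0.42 (n = 10; limma adjusted p = 0.000154) and CCNG1 by 0.35 ± 0.25 (adjusted p = 0.00879). BBC3, a pro-apoptotic gene, rose by 0.70 ± 0.64 (limma adjusted p = 0.0115), and FDXR by 0.47 ± 0.51 (adjusted p = 0.0296). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 0.44 ± 0.53 (limma adjusted p = 0.0484), a call lost in 7 of the 10 fits that left out a line (adjusted p between 0.0303 and 0.109). Over the 18 targets the mean was 0.11 ± 0.17 (sign-flip adjusted p = 0.225).

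Lysosomal and stress genes leaned upward. Of 24 lysosome genes, 8 rose and 1 fell, and adjusted over the list alone 10 rose and 2 fell. TFEB, a transcription factor of lysosomal genes, rose by 0.53 ± 0.32, the protease CTSA by 0.53 ± 0.35 and the autophagy receptor SQSTM1 by 0.54 ± 0.44, while GLA, a galactosidase, fell by 0.34 ± 0.24 (n = 10; limma adjusted p = 0.00214, 0.00328, 0.00829 and 0.00937). The lysosome list had a mean of 0.18 ± 0.14, above 0 in 10 of 10 lines (camera adjusted p = 0.011, sign-flip adjusted p = 0.0547, camera adjusted p = 0.987 with an estimated correlation). Of 20 genes of the unfolded protein and amino acid stress responses, 3 rose and 1 fell, and adjusted over the list alone 1 rose. HERPUD1 rose by 0.40 ± 0.36, PPP1R15A by 0.57 ± 0.66 and ATF4 by 0.42 ± 0.48, while the endoplasmic reticulum chaperone HSP90B1 fell by 0.25 ± 0.27 (limma adjusted p = 0.016, 0.0347, 0.04 and 0.0487). These stress genes had a mean of 0.29 ± 0.43 (camera adjusted p = 0.0262, sign-flip adjusted p = 0.225, camera adjusted p = 0.987 with an estimated correlation). Of 40 cytosolic ribosomal protein genes, 4 rose, and 0 adjusted over the list alone, with RPS27 at 0.38 ± 0.32 and RPL12 at 0.36 ± 0.38 (limma adjusted p = 0.0136 and 0.0316). That list had a mean of 0.16 ± 0.27, or 0.089 without NCIH1563 (camera adjusted p = 0.000277, sign-flip adjusted p = 0.23, camera adjusted p = 0.987 with an estimated correlation).

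Genes of RNA-binding proteins moved in both directions. Of 31 hnRNP and RGG protein genes, 2 rose and 2 fell, also adjusted over the list alone. RBM3, a cold-induced RNA-binding protein, rose by 0.72 ± 0.42 and HNRNPA1 by 0.29 ± 0.23, while HNRNPA3 fell by 0.52 ± 0.47 (n = 10; limma adjusted p = 0.00115, 0.0165 and 0.0126). Over the list the mean was −0.04 ± 0.19 (sign-flip adjusted p = 0.677). Of 26 genes of SR proteins and splicing kinases, 1 rose and 2 fell, also adjusted over the list alone. The kinase gene CLK3 fell by 0.50 ± 0.19, SRSF10 fell by 0.38 ± 0.29 and RBM39 rose by 0.23 ± 0.13 (limma adjusted p = 0.000405, 0.00929 and 0.0164), with a list mean of −0.06 ± 0.13 (sign-flip adjusted p = 0.358).

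Metabolic groups differed in the share of members past the test. Of 28 genes of oxidative phosphorylation, 5 fell and 0 rose, also adjusted over the list alone, with UQCRQ falling by 0.31 ± 0.17 and SDHC by 0.30 ± 0.15 (n = 10; limma adjusted p = 0.00555 and 0.0051). The list mean was −0.09 ± 0.09 (camera adjusted p = 0.0503, sign-flip adjusted p = 0.182). Of 13 genes of the mitochondrial genome, MT-ND5 rose by 0.39 ± 0.38 (limma adjusted p = 0.022) and 12 did not pass, also adjusted over the list alone (list mean 0.06 ± 0.25, sign-flip adjusted p = 0.648). Of 13 genes of hypoxia and glycolysis, ADM, a vasodilator peptide, rose by 0.72 ± 0.59 and 3 fell, also adjusted over the list alone, among them BNIP3 by 0.42 ± 0.45 and PGK1 by 0.31 ± 0.29 (limma adjusted p = 0.00709, 0.0329 and 0.0294). That list had a mean of 0.01 ± 0.22 (sign-flip adjusted p = 0.92). Of 20 genes of cholesterol synthesis, 1 fell and 0 rose, and 0 changed adjusted over the list alone (list mean −0.07 ± 0.26, sign-flip adjusted p = 0.648). Of 28 MYC targets and ribosome biogenesis genes, 2 rose and 1 fell, and 0 adjusted over the list alone, with MYC at 0.29 ± 0.31 (limma adjusted p = 0.0436; list mean −0.01 ± 0.16, sign-flip adjusted p = 0.92). Of 15 heat shock and immediate early genes, 3 fell, and 4 adjusted over the list alone, led by the chaperonin HSPE1, which fell by 0.34 ± 0.19 (limma adjusted p = 0.00442; list mean 0.04 ± 0.20, sign-flip adjusted p = 0.682).

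Lists of 11 NRF2 targets, 12 MAPK output genes, 5 epithelial junction genes and 3 mesenchymal and matrix genes had 0 members past limma's adjusted p over all genes and 0 adjusted over the list alone. Their means were 0.07 ± 0.16, 0.06 ± 0.59, 0.13 ± 0.28 and 0.34 ± 0.72 (n = 10; sign-flip permutation adjusted p = 0.386, 0.849, 0.371 and 0.386). Without EBC1 the NRF2 mean was 0.029 and the MAPK mean 0.16, and without NCIH1563 the MAPK mean was −0.072, the epithelial mean 0.079 and the mesenchymal mean 0.17. COL1A1 stood at 0.54 ± 0.91, CYR61 at 0.34 ± 0.86 and VIM at 0.13 ± 0.59, and KRT7 at 0.51 ± 0.74, KRT19 at −0.18 ± 0.23, TJP1 at 0.13 ± 0.50, KRT18 at 0.11 ± 0.54 and KRT8 at 0.08 ± 0.53. The other 8 lists had too few members in all lines for a test. In them, MUC1, an alveolar and airway mucin, rose by 0.99 ± 0.85, the chemokine CXCL16 rose by 0.69 ± 0.72, and TUBB3, a neuronal tubulin, fell by 0.34 ± 0.38 (limma adjusted p = 0.00774, 0.0208 and 0.0412). S100A2, of the squamous list, stood at 0.40 ± 0.80 (limma adjusted p = 0.197), and ENO2 at −0.16 ± 0.55.

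The exact two-sided sign-flip permutation test over the 10 lines placed 0 of 28 lists past the threshold after adjustment and 6 without adjustment. Its smallest adjusted p was 0.0547, for the lysosome list at the smallest p that 10 lines allow. A single list at that p cannot pass after adjustment over 28 lists, however alike the lines are. The sign-flip adjusted p-values are therefore no evidence that a list did not change. Camera with a preset correlation of 0.01 called 5 lists: mitosis, DNA replication, ribosomal proteins, lysosome and stress responses. With an estimated correlation, camera called 0 lists. Without NCIH1563, camera called only the mitosis and DNA replication lists, and the stress list was also lost without LK2 or NCIH1975 (adjusted p = 0.0675 and 0.0686). Without SW900, camera called the type I interferon list (adjusted p = 0.0346), and without PC9 the sign-flip test called the mitosis, homologous recombination and lysosome lists (adjusted p = 0.0365 for each). With a line left out, a single list at the smallest sign-flip p has an adjusted p of 0.109. Those sign-flip calls thus rest on several lists reaching it together. The mean and the median of the members or camera's direction differed in sign for the lists of type I PRMT genes, other PRMT genes, nucleic acid sensing, MYC targets, heat shock, hypoxia and NRF2 targets.

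**Figure D3:**
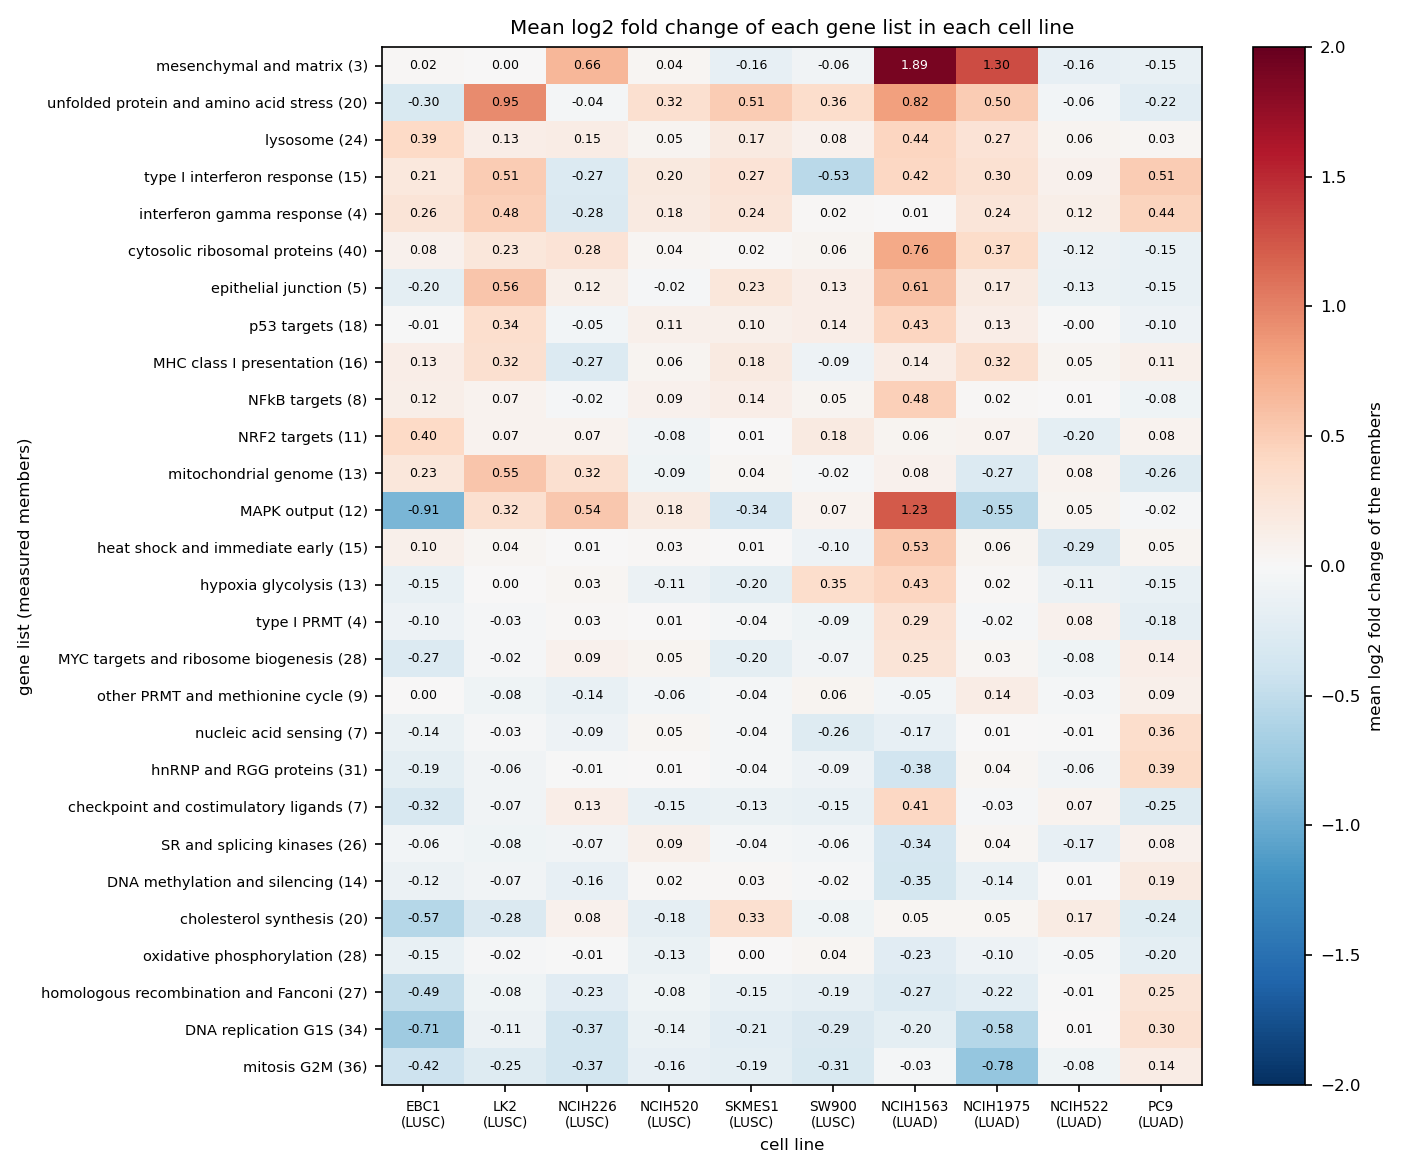
Mean log2 fold change of the members of each of 28 gene lists in each cell line, with the number of members in brackets and color from blue (lower with GSK3368712) to red (higher). The type I interferon list ranged from −0.53 in SW900 to 0.51 in LK2 and PC9, and the lysosome list was above 0 in 10 of 10 lines.

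The fourth comparison asked which lines carried each group, from the authors' calls and camera on the DESeq2 statistic within each line. Of 341 tests of a list in a line, 100 passed with the preset correlation, and 1 statistic per gene and line allowed no estimated correlation. Across lines, every camera call was lost with an estimated correlation, so camera's p-values within a line may be far too small. They take genes as units and do not measure the spread between cultures of a line. The statistics were not corrected for trends on GC content and transcript length. Such trends took 23.8% of the variance of the fold changes in NCIH1563 and 19.3% in PC9. List calls in these lines may partly reflect the trends, which was not tested. Type I interferon response genes moved in opposite directions. In SW900, 37 of 41 listed members were lower and 0 higher (mean −0.59, camera adjusted p = 4.39e-38). In PC9, 13 of 36 were higher and 0 lower (mean 0.97, camera adjusted p = 8.00e-17). In EBC1, LK2 and SKMES1, 18 of 34, 11 of 23 and 18 of 36 members were higher, against 5, 2 and 2 lower (camera adjusted p = 0.0297, 0.0362 and 5.71e-05). IRF7 stood at −0.50 in SW900, against 1.11 in EBC1 and 1.20 in LK2, in the authors' deposited table. In SW900, of 18 nucleic acid sensing genes listed, 9 were called lower, 2 higher and 7 neither (mean −0.32, camera adjusted p = 7.89e-06).

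MHC class II genes, which present antigen to CD4 T cells, were higher in 4 of the 7 lines in which they could be tested. The counts of higher members were 8 of 8 in EBC1, 7 of 8 in NCIH1975, 4 of 4 in NCIH1563 and 4 of 8 in SW900, with 0 lower members in each. Their means were 1.33, 1.48, 1.78 and 0.46 (camera adjusted p = 0.000213, 1.54e-05, 0.00578 and 0.0351). Interferon gamma response genes were higher in EBC1, LK2, SKMES1 and NCIH1975, where 12 of 18, 2 of 6, 10 of 19 and 5 of 17 members were called higher (camera adjusted p = 0.000317, 0.00148, 0.0125 and 0.000738). MHC class I genes were higher in LK2, SKMES1 and NCIH1975 (8 of 17, 10 of 20 and 1 of 20 called higher; camera adjusted p = 0.0464, 0.00425 and 0.0469) and lower in NCIH226 (11 of 20 called lower, adjusted p = 7.51e-05). Checkpoint and costimulatory ligands were lower in EBC1 (9 of 17 called lower) and SKMES1 (6 of 15; camera adjusted p = 0.0382 and 0.0109). In NCIH1563, 8 of 11 chemokine and cytokine genes were higher (mean 2.02, camera adjusted p = 2.65e-07), as were 9 of 15 NF-kB targets (mean 0.71, adjusted p = 0.00793).

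Mitosis genes were lower in 7 of 10 lines, from 28 of 36 members in EBC1 (camera adjusted p = 2.41e-08) to 12 of 36 in NCIH1975 (mean −0.78, adjusted p = 1.42e-11). DNA replication genes were lower in 7 lines, with 34 of 35 members lower in EBC1 (mean −0.73, camera adjusted p = 3.50e-20). In PC9 that list passed upward, at a mean of 0.30, with 0 of 34 members called by the authors (camera adjusted p = 0.0341). Stress response genes were higher in 6 lines, led by LK2 with 18 of 22 (mean 0.92, camera adjusted p = 1.97e-19), and lower in EBC1 with 11 of 22 (mean −0.27, adjusted p = 0.0226). MAPK output genes, feedback and target genes of the ERK pathway, were lower in EBC1 (19 of 20, mean −0.83), SKMES1 (14 of 21, mean −0.39) and NCIH1975 (4 of 19, mean −0.61), with camera adjusted p = 3.50e-16, 7.66e-10 and 1.12e-05. The same list was higher in NCIH1563 (12 of 19, mean 0.89), NCIH226 (8 of 17, mean 0.53) and NCIH520 (6 of 19, mean 0.24), with camera adjusted p = 4.03e-06, 0.0081 and 0.0362. Cholesterol synthesis genes were lower in EBC1, with 20 of 22 lower (mean −0.60, camera adjusted p = 5.34e-08), and in LK2, NCIH520 and PC9. They were higher in SKMES1, with 12 of 21 higher (mean 0.32, adjusted p = 9.91e-05).

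Lineage lists passed in few lines. Squamous keratinocyte genes were higher in SW900 (4 of 5, mean 1.62, camera adjusted p = 2.81e-19) and NCIH1975 (4 of 11, mean 0.73, adjusted p = 0.00629). Alveolar and airway genes were higher in SW900 (6 of 9, mean 1.07, camera adjusted p = 5.95e-08). Mesenchymal and matrix genes were higher in NCIH1563 (12 of 24), NCIH1975 (10 of 22) and NCIH226 (8 of 26), with camera adjusted p = 5.02e-05, 3.77e-08 and 0.000553. Epithelial junction genes were higher in SKMES1 (7 of 14, mean 0.35, camera adjusted p = 0.0135) and lower in NCIH1975 (3 of 23, mean −0.41, adjusted p = 0.00259). Among markers of other cell types, the stromal and endothelial list was higher in NCIH1975 (2 of 5, camera adjusted p = 0.00549) and the immune lineage list in PC9 (1 of 4, adjusted p = 0.0464). The neuroendocrine and neuronal list was lower in PC9 (2 of 4, adjusted p = 0.0269). Cancer-testis antigens, tested in 4 lines, passed in 0 of them. The lists of type I PRMT genes, other PRMT genes, DNA methylation and splicing kinases also passed in 0 lines.

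The fifth comparison asked which genes responded differently between lines. LBH stood at 4.91 in EBC1 and −1.52 in LK2 in the authors' deposited table and had the largest Cochran's Q (1042, 9 degrees of freedom) among the genes with a line above 1 and a line below −1. ASNS, PCK2, PSAT1 and CHAC1 followed, at Q of 557, 490, 477 and 450. ASNS makes asparagine, PSAT1 acts in serine synthesis, PCK2 is the mitochondrial phosphoenolpyruvate carboxykinase and CHAC1 degrades glutathione. ETV4, a transcription factor of the MAPK output list, was sixth at 333. Over all 10 lines the mean of LBH was 0.89 ± 1.68, or 0.44 without EBC1, and that of CHAC1 was 0.82 ± 1.48 (n = 10). In all, 6157 of 9339 genes (65.9%) differed between lines after adjustment, and 140 had both a line above 1 and a line below −1. The test takes the authors' standard errors as given, and these rest on 2 libraries per arm.

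Fold changes were then correlated across the 9339 genes for each of 45 pairs of lines. Pearson's r had a median of 0.401 and ranged from −0.197 for NCIH1563 and PC9 to 0.614 for SKMES1 and SW900. Pairs of LUSC lines lay between 0.419 and 0.614, pairs of LUAD lines between −0.197 and 0.529, and mixed pairs between 0.176 and 0.509. A smooth trend on GC content and transcript length took 23.8% of the variance of the fold changes in NCIH1563 and 19.3% in PC9, against 0.587% to 3.48% in the LUSC lines. After removal of the trends, r between NCIH1563 and PC9 was −0.0248. These correlations are across genes, which are not independent replicates, so no p is given.

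**Figure D4:**
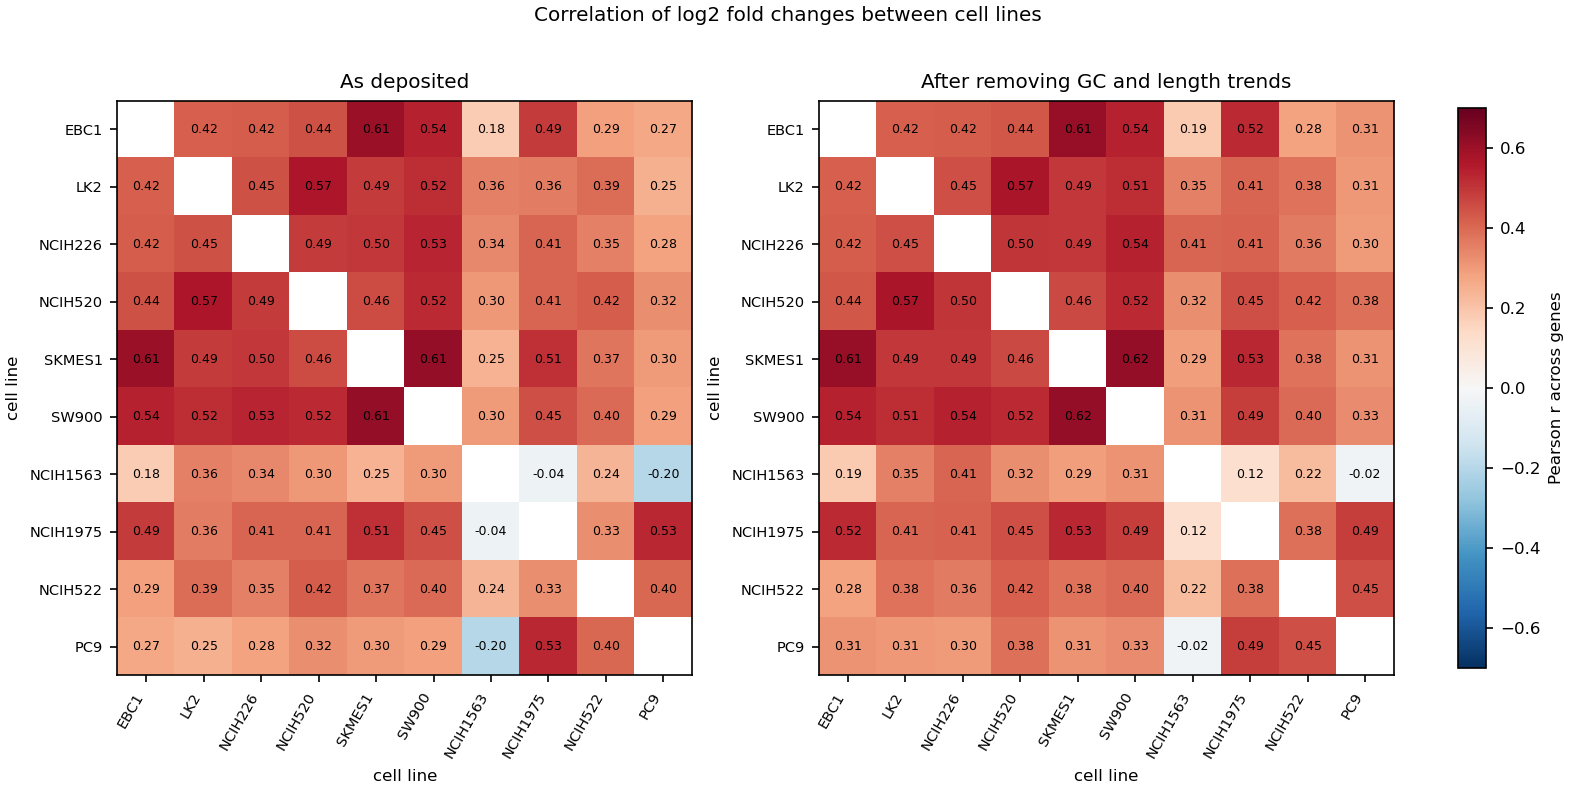
Pearson correlation across genes of the log2 fold changes of each pair of the 10 cell lines, as deposited (left) and after removal of trends on GC content and transcript length (right). The LUSC pairs lie between 0.419 and 0.614 as deposited, and the pair of NCIH1563 and PC9 moves from −0.197 to −0.0248.

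The last comparison, added after the row labels were seen, set the 4 LUAD lines against the 6 LUSC lines. ATL3, an endoplasmic reticulum shaping GTPase, fell more in the LUAD lines, at −1.53 ± 0.23 (n = 4) against −0.40 ± 0.15 (n = 6), a difference of −1.12 (limma adjusted p = 0.0308). It was the only gene past the test by limma, and 511 genes had an unadjusted p under 0.05. After removal of the GC content and length trends, 0 genes passed, with ATL3 at a difference of −1.07 (limma adjusted p = 0.0643). Leaving out a line gave between 0 and 14 genes, with 14 without NCIH1563 and 0 without any 1 of EBC1, LK2, NCIH226, NCIH520, SW900, NCIH1975 and PC9. The ATL3 difference itself stayed between −1.06 and −1.23 whichever line was left out (limma adjusted p between 0.0194 and 0.185). The next genes, picked out after their values were seen, were HIST2H2AA3 at −0.93 ± 0.11 in LUAD against 0.24 ± 0.37 in LUSC lines, and ABI2 at −1.39 ± 0.24 against −0.51 ± 0.18, which did not pass (limma adjusted p = 0.153 for each). The exact permutation test placed 0 of 28 lists past the threshold, with 0 at an unadjusted p under 0.05. The LUAD lines also had the larger standard errors and trends on GC content, so subtype and these properties cannot be told apart.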

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

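The tests of fold change size in NCIH1975, PC9 and NCIH522, the test for exchanged libraries in PC9, the comparison of LUAD with LUSC lines and the GC content and length correction were chosen only after the data were seen.

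Lines were checked for a value far from the other 9 in 69 sets of 10 lines, and 9 sets had one. Chance alone gives about 1 in 20 independent sets. Some sets were genes chosen for large differences between lines, and all sets share the lines, so this rate is no yardstick for the count. HDAC5 was 3.57 and HDAC4 −4.87 in NCIH1563, each far from its values in the other lines. In the same line, the means of the NF-kB and heat shock lists were 0.48 and 0.53, and CARM1 was 0.98. LBH stood at 4.91 in EBC1, ATP6V1G2-DDX39B at 3.59 in NCIH1975 and SCOC-AS1 at −2.33 in NCIH226. The nucleic acid sensing list had a mean of 0.36 in PC9, against −0.26 to 0.05 in the other lines.

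Fold changes differed between lines by more than the authors' standard errors for 6157 of 9339 genes, by Cochran's Q. The labels do not say whether the 2 libraries per arm behind these errors are separate cultures, so the count does not separate a line's response from variation between its cultures. The count included 18 of the 24 genes named across the lines. Among genes with opposite changes, Q was 1042 for LBH, 557 for ASNS, 490 for PCK2, 477 for PSAT1, 450 for CHAC1 and 333 for ETV4. ATL3 fell more with GSK3368712 in LUAD than in LUSC lines by a test of the difference itself, at −1.12. For that comparison, 2 of 100 splits drawn from the 210 splits of the lines into 4 and 6 gave as many genes, the real one included. The real value was 1 and the highest of the other splits was also 1, for EBC1, LK2, SKMES1 and NCIH1975 against the rest. Because another split ties it, and the ATL3 call was lost in 8 of the 10 fits that left out a line, this count is a weak basis for excluding chance. For the count across lines, 1 of 100 sign assignments drawn gave as many genes, the real one (2021, against at most 1 in the others). This argues against a chance agreement in direction between the lines. The test asks only whether the lines share a direction, not what causes it.

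NCIH1975, NCIH522 and PC9 had far fewer called genes than the LUSC lines. With noise added to the LUSC lines up to the standard errors of these 3 lines, the median count of calls fell to 569.5, so larger standard errors may account for the low counts in NCIH1975 and PC9. For NCIH522 the LUSC lines kept 321 to 1695 calls at its standard errors, all above its 215. Its noise-corrected SD of fold changes was 0.0849, below the lowest LUSC value of 0.239, and 0 after removal of GC content and length trends. An SD of 0 means that its fold changes spread no more than its standard errors alone predict. After the same removal its correlation with the other lines lay between 0.219, for NCIH1563, and 0.453, for PC9. The standard errors may therefore overstate its noise, and these values cannot decide whether its response was smaller. In NCIH1975 the noise-corrected SD as deposited, 0.348 (jackknife SE 0.00815), lay above the LUSC median of 0.309, which argues against smaller fold changes. After removal of GC content and length trends it was 0.316 (jackknife SE 0.0089) against 0.308. It was then above that median by less than its jackknife SE, which leaves smaller fold changes open. In PC9 smaller fold changes cannot be told apart from noise. Its SD of 0.336 (jackknife SE 0.0143) was above that of 4 of the 6 LUSC lines as deposited but 0.263 after removal of the trends.

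The fold changes of NCIH1563 and PC9 correlated at −0.197. An exchange of treated and DMSO libraries in PC9 is argued against by its median r of 0.291 with the other 8 lines, of which the lowest was 0.247. Removing trends on GC content and transcript length moved r to −0.0248 (jackknife SE 0.0171). Most of the negative correlation may therefore reflect these trends, but r stayed below 0 by less than 2 jackknife SEs and below 0.283, the lowest r of a mixed pair without NCIH1563 after the same removal and the bar set for this test, so this explanation is left open. The treatment response itself could also follow gene length or GC content, which was not tested.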

How the results depend on the processing

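Tests with the GC content and length correction, the subsets of lines by subtype or standard error, and LUAD against LUSC were chosen only after the data were seen. No paired analysis was possible because values per library were not analysed here. For the same reason the planned limma fit on libraries, the replicate block and the omission of each replicate were not run.

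Of the results for named genes, 716 kept their direction and side of the threshold, 37 lost the call, 3 gained it and 2 reversed. For lists these were 399 the same, 3 gained and 18 reversed, and for the main counts 88 the same and 17 changed by over 1.5 times. With the top 75% of genes by expression, there were 126 genes changed in NCIH522, 277 genes changed in PC9 and 1268 across lines, where fewer genes were tested. A random-effects meta-analysis gave 3751 genes across lines, 2003 of them shared, and the 4 LUAD lines alone gave 4, with fewer lines. Camera with an estimated correlation called 0 lists. Leaving out each line gave 1563 to 2682 genes across lines, 0 to 3 lists by sign flip (3 without PC9), 2 to 7 lists by camera (2 without NCIH1563) and 0 to 14 genes for LUAD against LUSC (14 without NCIH1563). For the latter, 0 remained after GC content and length correction. Camera also called the homologous recombination list without LK2, NCIH522 or PC9 (adjusted p = 0.0491, 0.0268 and 0.00385), and the oxidative phosphorylation list without LK2, NCIH226, SKMES1, SW900 or NCIH522 (adjusted p between 0.0189 and 0.0421). With centring it called both (adjusted p = 0.0495 and 0.0489), and without NCIH1975, NCIH522 and PC9 together it called homologous recombination and the mitochondrial genome (adjusted p = 0.00156 and 0.0379). Most losses for named genes came with the LUAD lines alone or concerned CDKN1A. The cause was not tested for the meta-analysis, the lines left out and the correction.

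Leaving out a line reversed some means without a call. It gave −0.11 to 0.29 for PCK2 and −0.087 to 0.37 for ETV4. For lists it gave −0.037 to 0.015 for type I PRMT genes, −0.029 to 0.0029 for other PRMT genes, −0.036 to 0.022 for MYC targets, −0.072 to 0.16 for MAPK output, −0.0098 to 0.081 for heat shock and −0.036 to 0.034 for hypoxia. Medians of members were 0.058 for type I PRMT genes, 0.029 for nucleic acid sensing, −0.045 for heat shock and −0.044 for hypoxia. Type I PRMT genes were at 0.011 without NCIH1975, NCIH522 and PC9. Leaving out a line moved the mean by over 1.5 times or in sign for 18 of 28 lists, of which camera called only the ribosomal protein list. The cause was not tested.

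The authors' standard errors rest on 2 libraries per arm, genes below the authors' expression filter have no value, and depth per library was not analysed here, so absence from the table of a line does not show that a gene did not change.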

Other observations

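The GC content and length correction and the list of snoRNA hosts were chosen only after the data were seen, when SNHG19 and SNHG8 had been found to rise, and the genes named here were chosen after their values were seen.

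Genes with values in 7 to 9 lines held further large changes. Of 2772 tested by limma, 239 rose and 189 fell. NUPR1, a stress-induced chromatin protein, rose by 2.79 ± 1.78 in 9 lines (limma adjusted p = 0.00346), and SLPI, a secreted protease inhibitor, by 1.80 ± 1.37 in 8 lines (limma adjusted p = 0.013). MGMT, the DNA repair methyltransferase that removes alkyl groups from guanine, and LMF1, a lipase maturation factor, had means of −1.83 ± 1.10 in 9 lines and −3.41 ± 1.44 in 7 (limma adjusted p = 0.00288 and 0.000992). FCER1G, the common signalling chain of Fc receptors, had a mean of 2.20 ± 1.06 in 6 lines and was called higher by the authors in 5. The spliceosomal RNA genes RNU6ATAC and RNVU1-15 had means of 2.29 ± 1.03 and 1.99 ± 0.88 in 7 lines (limma adjusted p = 0.00174 for each). The libraries were made with an mRNA kit, so these values are uncertain as measures of spliceosomal RNA levels.

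Long non-coding transcripts that host snoRNAs rose as a group. Of 23 hosts, 19 had values in all lines, 15 rose and 0 fell. The 19 were SNHG genes, GAS5 and ZFAS1. TMEM107, which overlaps SNORD118 and fell, was not among them. The 17 hosts outside the named genes had a mean log2 fold change of 0.44 ± 0.21, above 0 in 10 of 10 lines (exact sign-flip permutation p = 0.00195, the smallest that 10 lines allow), and 13 of them rose.

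GC content and length trends are argued against as the whole cause, since the mean of the 17 hosts after their removal was 0.452 ± 0.211. A general rise of long non-coding RNAs of similar expression is argued against too: the hosts' median of 0.43 lay at percentile 100 of 10000 random lists of other long non-coding genes, whose median was 0.12. A hypothesis that remains open is that GSK3368712 may raise long non-coding snoRNA host transcripts as a class. It was found and tested on the same data, and no mechanism was tested.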
